A study of Oryza sativa with 4 samples.

How the data were processed

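Gene expression was measured in leaves of 7-day-old rice seedlings (Oryza sativa) with 4 one-colour Agilent arrays. The plants were wild type or overexpressed OsDIS1, a RING-finger E3 ubiquitin ligase of the SINA family, and leaves were taken under normal conditions or after drought. Per the labels' protocols, untreated seedlings were sampled first and the others were moved onto filter paper. Their leaves were taken once the overexpression plants showed drought symptoms, so the drought leaves were collected later. The time of day of either collection is not given in the sources used here. Each combination of genotype and condition was 1 array, so no replicate spread exists, no test was run, and no p-value or standard error is given. All 4 arrays were on 1 slide with 1 scan date.

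Per the labels' protocols, total RNA was purified, amplified and labelled with Cy3 in a single colour. Per the file headers, the scanner files were made with Agilent Feature Extraction 10.5.1.1 for array design 015241, while the submitters' processing notes name version 10.7. The intensity of each spot deposited by the authors is a processed signal, which is background-subtracted per the file headers. The deposited value table holds log2 values of the same arrays, with scale and normalization unstated. Its columns all have a median of 10.8, the same quartiles within 0.01 of rounding, and correlations across probes of 0.999 to 1.00 with their own arrays. They lay close to quantile-normalized log2 intensities, with a median absolute difference of 0.0362 to 0.039, and were used as an alternative. The direction of the table's values follows the scanner signals. Its exact scaling stays unknown.

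Each array held 45151 spots, of which 43734 were not controls. After leaving out spots marked as outliers and the probes of design controls, 42303 probes were used. No spot was saturated. The processed intensity was put on the log2 scale and the array's 75th percentile over non-control spots was subtracted. Spots of 1 probe were averaged, and a gene with several probes was represented by the probe with the highest mean over the 4 arrays. This gave 29617 loci under identifiers of the Rice Annotation Project and 529 probes without a locus, called genes together. Gene descriptions are those of the array files and can be old. The gene table supplied as a reference matched 0 loci and was not used. For 1122 loci a probe sequence was shared with another locus, and each such locus was counted as a gene.

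A gene was compared if it was well above background on at least 1 of the arrays compared, and it was counted if it differed by 2-fold or more. A gene not well above background on 1 side has only a bound there, given as at least N-fold. The bound sets the bright array's value over the higher of 2 values on the dim array, its lowest signal among probes well above background and the probe's own signal. The only error available is technical. It was taken as the SD, over spots of identical sequence on the same arrays, of each difference, pooled over 2901 to 2983 sequences. The largest SDs of single sequences were capped before pooling, which lowers the pooled SD. That SD was 0.10 for overexpression against wild type under normal conditions and 0.09 under drought. It was 0.11 for drought in either genotype and 0.13 for the difference of both responses. For sequences not well above background it was 0.64 to 1.04. It leaves out all variation between plants and between labellings.

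The comparisons were overexpression against wild type in each condition, drought against normal conditions in each genotype, and the difference of both drought responses. Similarities were given as Pearson correlations across genes, which are not independent replicates, and as overlaps beside the number expected for independent lists. Because the genotype difference under drought and the wild type drought response share an array, noise alone was simulated 100 times from the technical SD. Lists of 33 kinds were fixed by locus or description: construct and reported partners, SINA-type E3 ligases, drought positive control, LEA proteins and dehydrins, ABA synthesis and breakdown, ABA signalling, drought-related transcription factors, osmolyte synthesis, aquaporins, antioxidant enzymes, glutathione S-transferases, class III peroxidases, heat shock proteins and factors, photosynthesis, cytosolic and plastid-type ribosomal proteins, histones, cell cycle and DNA replication, cell wall loosening and synthesis, jasmonate, pathogenesis-related, WRKY, NAC and AP2/ERF factors, chlorophyll breakdown and leaf senescence, circadian clock, low-oxygen response, nitrate and phosphate nutrition, diterpenoid phytoalexins, root markers, seed storage and germination, shoot meristem markers, and reference genes. A list's median was placed among 10000 random lists of equal size matched on mean signal, in 20 bins. That percentile describes these arrays only.

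Named genes followed a rule. Among genes with an informative description (17492 loci), it takes the 8 highest and 8 lowest measured on both arrays, up to 3 per direction with a bound only, and up to 4 per direction and list. OsDIS1, its reported partner OsSKIPa and the drought marker OsLEA3 are always addressed, though no probe carries the OsDIS1 locus. The rule as planned also included every member given by locus. Such members count in their lists, but not all of them are named here. The comparisons, lists, naming rule and alternatives were set before the data were examined, except for the last 2 alternatives. The alternatives were quantile normalization, scaling to the median, normexp background correction with an offset of 50, the value table, a filter on every array compared, no filter, the mean over a gene's probes, each probe on its own, and thresholds of 1.5-fold and 4-fold. A common floor on dim signals, at the highest 95th percentile of random and artificial control probes over the arrays (-6.73 on the normalized log2 scale), and counting each probe sequence once, under the first locus in name order, were added after the data were seen.

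The counting step was tested on simulated data for 23835 genes measured on all 4 arrays, with 200 genes changed. In each of the 5 comparisons it called 0% of genes changed by 1.5-fold, 100% of those changed by 2.5-fold or 4-fold, and 0 unchanged genes. The simulated noise was the technical SD of sequences above background, small beside 2-fold, so this outcome was largely fixed in advance. It tells nothing about dim genes or variation between plants. On the arrays, differences varied by 2-fold or more among identical spots for 0.512% to 1.10% of sequences above background. In simulated lists of 20 genes for overexpression against wild type under normal conditions (23835 genes), 6% of unshifted lists fell outside the central 95% of random lists. That share was 84% for a shift of 0.1 and 96% for a shift of -0.1. These lists held technical noise alone, whereas the measured differences of genes above background on both arrays had an SD of 0.404. Shifts of that size are therefore harder to see in the real lists. For the 19 cell cycle and DNA replication genes, the central 95% of random lists ran from -0.183 to 0.045. Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9 was used, with R 4.3.3 and limma 3.58.1 for normexp.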

Results

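Leaf RNA of wild type rice seedlings and of seedlings overexpressing OsDIS1 was compared under normal conditions and under drought, with 1 array for each of the 4 groups. The share of probes well above background was 88.2% for wild type and 83.1% for overexpression plants under normal conditions, and 85.4% and 89.0% under drought. The median processed signal was 1445, 1493, 1643 and 2148 in the same order. With 1 array per group no difference has a replicate check, and the number of arrays limits the precision.

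The overexpressed gene itself was not analysed here, since no probe carries the locus identifier fixed for OsDIS1, and its level therefore could not be used to check the labels. OsSKIPa, a transcriptional co-regulator reported as a partner of OsDIS1, differed by -0.17 on the log2 scale between overexpression plants and wild type under normal conditions and by 0.07 under drought. All 9 SINA-type E3 ligase genes on the array differed by less than 2-fold in every comparison. OsLEA3, a late embryogenesis abundant protein used as the drought marker, was higher under drought by 6.54 in wild type and by 5.92 in overexpression plants. Its normalized levels were -4.03 and -3.36 under normal conditions and 2.51 and 2.55 under drought. Of 5 reference genes, OsAct1, which encodes actin, was lower under drought by 1.21 and 1.01, and the other 4 stayed within 2-fold.

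**Figure D1:**
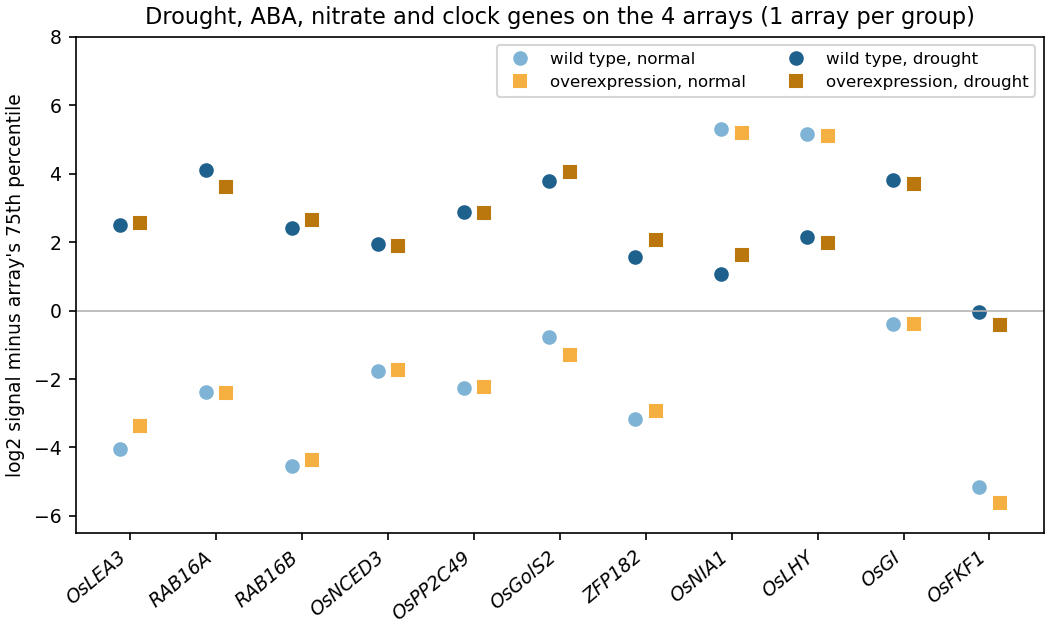
Normalized log2 signal (vertical axis, relative to each array's 75th percentile) of 11 genes for drought, abscisic acid, nitrate and the clock, with 1 point per array and 1 array per group. OsLEA3 stands at -4.03 and -3.36 under normal conditions and at 2.51 and 2.55 under drought.

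The first question was which genes differed with drought in wild type leaves. Late embryogenesis abundant proteins and dehydrins, which protect cells during water loss, were at least 2-fold higher for 22 of 30 detected members, with a median difference of 3.26. Among them, dehydrin 9 (Os11g0451700) was at least 1092-fold higher (253-fold with the dim array at the common floor for dim signals) and RAB16B was higher by 6.95. OsNCED4, OsNCED3 and OsNCED1, which encode carotenoid-cleaving enzymes that commit the pathway to abscisic acid (ABA), were higher by 7.48, 3.72 and 3.22. In ABA signalling 13 of 25 genes were higher and 0 lower, led by the protein phosphatases OsPP2C49 (5.16) and OsPP2C08 (4.40), of a class that restrains the ABA signal. ABA synthesis and breakdown had 5 of 10 genes higher and 1 lower.

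Transcription factors and osmolyte enzymes of wild type also differed with drought. The zinc finger gene ZFP182 was higher by 4.73 and OsDREB1C by 4.52, while OsDREB1A was lower, at -2.21. Of 15 drought-related transcription factors, 6 were higher and 2 lower. OsGolS2, which makes galactinol for raffinose sugars, was higher by 4.56, and osmolyte synthesis had 7 of 23 members higher and 4 lower, the latter 2 with both arrays above background. WRKY factors were higher for 26 of 69 members and lower for 8, NAC factors for 15 and 7 of 60 (13 and 4 of the 54 above background on both arrays), and AP2/ERF factors for 13 and 6 of 53. Pathogenesis-related genes, which encode defence proteins, were higher for 60 of 141 members and lower for 15, with OsPR1a at 6.37. Diterpenoid phytoalexin genes were higher for 5 of 6, and for 3 of the 4 above background on both arrays, with the diterpene synthase OsKSL4 at 3.57 (2.59 with the common floor).

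Senescence and clock genes also differed between the wild type arrays. Of 8 genes for chlorophyll breakdown and leaf senescence, 6 were higher, including Osl85 (isocitrate lyase, a glyoxylate cycle enzyme) by at least 1121-fold (412-fold with the common floor) and the regulator OsNAP by 3.02. In the circadian clock list 6 of 9 genes were higher, with OsFKF1 at 5.10 and OsGI at 4.21, and the dawn-phased OsLHY was lower, at -2.99. The drought leaves were collected later than the normal leaves, at a time of day that is not given.

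The early light-inducible protein genes Os07g0178800 and Os07g0178700 differed by -7.84 and -7.24 in wild type. Nitrate reductase, which reduces nitrate to nitrite, was lower for OsNIA1 (-4.24) and by at least 278-fold for Os02g0770800 (66.3-fold with the common floor). In the nitrate and phosphate nutrition list 7 of 21 members were lower and 2 higher, and its median of -0.33 turned to 0.062 with both arrays above background. Photosynthesis genes had 23 of 97 members lower and 5 higher, with a median of -0.30. Class III peroxidases, which act in cell walls, were lower for 45 of 114 members and higher for 4, and lower for 26 of the 93 above background on both arrays, and histones were lower for 18 of 47 with 0 higher.

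In total, 3179 genes were at least 2-fold higher and 4301 lower under drought in wild type, among 26517 compared. With both arrays above background there were 2849 and 3151 of 24623. With all arrays held at the common floor they were 2866 and 3093 of 26517. Scaling to the array median moved the median of all genes by -0.13 in this comparison, by -0.23 in overexpression plants and by -0.10 in the difference of both. Quantile normalization moved the last 2 by -0.15 and -0.11.

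The same question was asked in overexpression plants. Late embryogenesis abundant proteins and dehydrins were higher for 23 of 30 members, with a median of 3.05 and with dehydrin 9 (Os11g0451700) at 7.61, RAB16B at 7.01 and OsEm at least 172-fold higher (79.1-fold with the common floor). OsNCED4 was higher by 7.86, OsNCED3 by 3.61 and OsNCED1 by 3.43, and ABA synthesis and breakdown had 4 of 10 genes higher. ABA signalling had 14 of 25 genes higher, with OsPP2C49 at 5.09 and OsPP2C08 at 4.75. OsGolS2 was higher by 5.36, and osmolyte synthesis had 9 of 23 members higher and 4 lower. The clock list again had 6 of 9 genes higher (OsFKF1 5.22, OsGI 4.09), with OsLHY at -3.13.

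Under drought in overexpression plants, senescence genes were higher for 6 of 8 members, with Osl85 at 7.49. Pathogenesis-related genes were higher for 68 of 141 and lower for 13, WRKY factors for 29 and 2 of 68, and drought-related transcription factors for 7 and 3 of 15. The early light-inducible Os07g0178800 differed by -8.08, nitrate reductase Os02g0770800 by -7.24 (-5.83 with the common floor) and OsNIA1 by -3.56. Plastid-type ribosomal proteins were fixed by description, without leaving out mitochondrial ones. They were lower for 24 of 47 members and higher for 5, with a median of -1.04 and a mean of -0.47 (18 positive). In wild type the same list had 3 of 47 members lower and a median of -0.52, and 0 of the 47 passed 2-fold in the difference of both responses.

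Overexpression plants had 4899 genes higher and 3246 lower under drought, of 26370. With both arrays above background they were 3631 and 3113 of 24151. The share of higher genes depended on the scaling, with 3684 higher and 3965 lower under quantile normalization, 3701 and 4383 under median scaling, and 3705 and 4053 in the authors' deposited table. Cytosolic ribosomal proteins had medians of 0.05 in wild type and 0.21 here, and of -0.073 and -0.023 under median scaling, which shifts all genes alike. Their percentiles among random lists were 99.5 and 100 under that scaling.

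Both drought responses were compared across genes. The correlation was 0.81 over 27100 genes and 0.903 over the 23835 genes above background on all 4 arrays. A total of 2763 genes were higher in both genotypes, where 594 were expected for independent lists, and 2598 were lower in both, where 565 were expected. These differences share no array. In the drought minus normal panel the points lie along the diagonal.

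**Figure D2:**
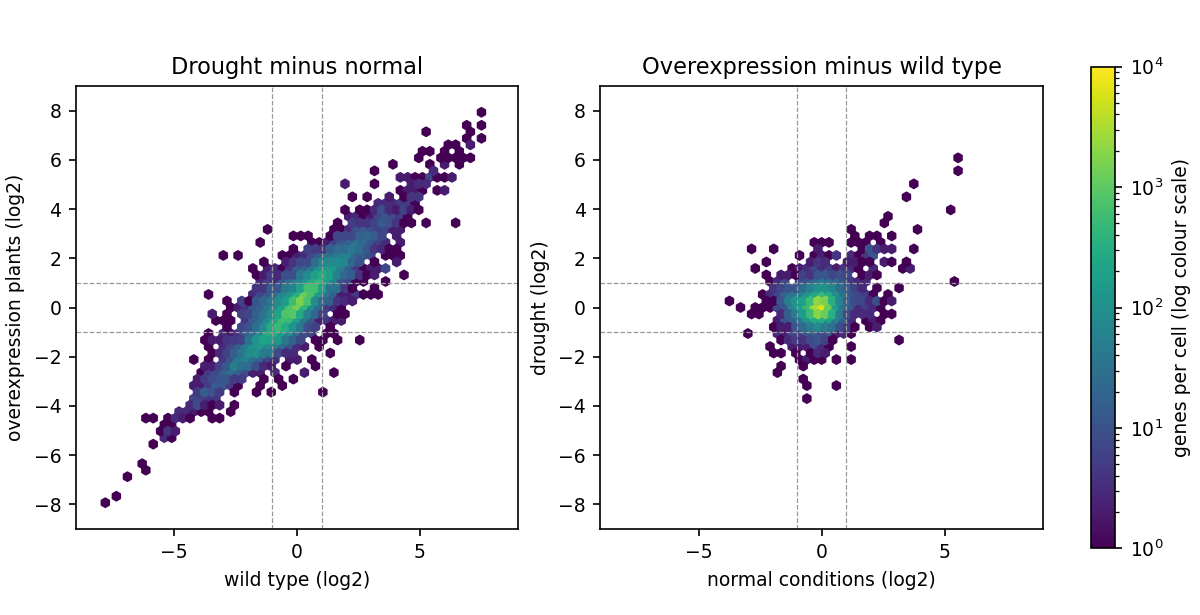
Log2 differences per gene for genes above background on all 4 arrays, as drought minus normal in wild type (horizontal) and overexpression plants (vertical), and as overexpression minus wild type under normal conditions (horizontal) and drought (vertical). Colour gives genes per cell on a log scale and dashed lines mark 2-fold. The correlations are 0.903 and 0.199.

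The second question was how overexpression plants differed from wild type under normal conditions. The gene described as RNase P-related, Os05g0270500, was at least 472-fold higher in overexpression plants, or at least 107-fold with the dim array at the common floor, and Os10g0567900, with an F-box interaction domain, was higher by 3.70. The retrotransposon gag gene Os05g0374700 was higher by 4.48 and the En/Spm-like Os03g0714800 by at least 56.5-fold (20.2-fold with that floor). OsPR1a was higher by 2.82, OsPR1b by 2.12 and OsKSL7 by 2.31. The pathogenesis-related list had 12 of 138 members higher and 4 lower (11 and 1 of the 131 above background on both arrays), and its median of -0.04 turned to 0.085 under quantile normalization, 0.016 under median scaling and 0.077 in the authors' deposited table. OsJAZ9 and OsJAZ13, which encode repressors of jasmonate signalling, were higher by 1.80 and 1.64.

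Among drought regulators, OsDREB1B, OsDREB1E and OsDREB1G, which bind dehydration-responsive promoter elements, were higher by 1.26, 1.22 and 1.01, and the drought-related factor list had a median of 0.17 (percentile 99.8 of random lists). A NAC-domain gene, Os01g0104200, was higher by 3.38 (2.32 with the common floor). Histones were lower for 16 of 47 members and higher for 0, with a median of -0.79 below all random lists. PCNA (Os02g0805200), the sliding clamp of DNA replication, differed by -1.39, and the small chain of ribonucleotide reductase (Os06g0127900), which makes deoxynucleotides, by -1.60. In the cell cycle and DNA replication list 5 of 19 members were lower, and 3 of the 17 above background on both arrays, with a median of -0.07 at percentile 46.6 of random lists that turned positive under quantile normalization and in the authors' deposited table.

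Further lower genes were the homeodomain-like Os04g0565300 (-3.76), the F-box gene Os06g0148300 (-2.91) and the ERF5-like Os01g0657400 (-2.41). A gene described as growth-regulating factor 3 (Os03g0674700) was lower by at least 17.0-fold, or 5.23-fold with the common floor. Class III peroxidases were lower for 26 of 114 members, and for 12 of the 96 above background on both arrays. Between genotypes under drought, 9 of 102 were higher and 3 lower. In the difference of both responses 38 of 116 were higher and 7 lower, and 19 and 6 of the 89 above background on all arrays. Plastid-type ribosomal proteins had a median of 0.20 (mean 0.06, 27 of 47 positive) and cytosolic ones of -0.10. Jasmonate genes had a median of 0.05 (percentile 99.8), of 0.18 under quantile normalization and 0.11 under median scaling, which turned to -0.002 with normexp correction.

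In total 392 genes were higher and 1730 lower of 26230, and 276 and 533 of the 24159 above background on both arrays. The split was 530 and 1012 under quantile normalization, 243 and 402 with normexp correction, and 534 and 1062 in the authors' deposited table. On the wild type array under normal conditions 31.7% of random and artificial control spots were well above background, against 10.8% on the overexpression array.

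The third question was how the genotypes differed under drought. In overexpression plants Os05g0270500 was again higher, by at least 457-fold or 109-fold with the common floor, and Os10g0567900 by 5.01. A nonspecific lipid transfer protein (Os11g0620300), of a family that carries lipids to the cell surface, was higher by 4.23, and the lectin-like beta-glucosidase aggregating factor Os12g0247700 by 3.06. Lipoxygenases, which start oxylipin synthesis, were higher by 2.22 (Os12g0560200) and 2.21 (Os12g0559200), and jasmonate genes had 6 of 39 members higher with a median of 0.19. WRKY factors had a median of 0.28, above all random lists, with 4 of 68 members past 2-fold.

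Genes on the lower side under drought were the zinc finger gene Os04g0608700 (-3.83), the disease resistance gene Os10g0161400 (-3.51, or -2.58 with the common floor) and the dimethyladenosine transferase Os02g0122900 (-3.07). OsEXPA14 (Os02g0267700), an expansin that loosens cell walls, was at least 39.2-fold lower (5.37-fold with the common floor) and the homeobox gene OSH15 at least 22.7-fold (3.07-fold with that floor). MADS23 (Os08g0431900) differed by -2.69 on its brightest probe (-1.41 with the common floor), and its other probe was not well above background in wild type. OsEm, an LEA protein, was higher by 1.90 and OsDREB1G by 1.11. Senescence genes had a median of -0.35, with 0 of 8 past 2-fold, and plastid-type ribosomal proteins one of -0.16. That of photosynthesis genes was -0.15, and -0.003 under quantile normalization and in the authors' deposited table.

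Counts were 779 genes higher and 263 lower of 26342, and 341 and 171 of the 24930 above background on both arrays. With normexp correction they were 268 and 176. Cytosolic ribosomal proteins had a median of 0.02, and of -0.028 under median scaling, which shifts all genes alike.

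**Figure D3:**
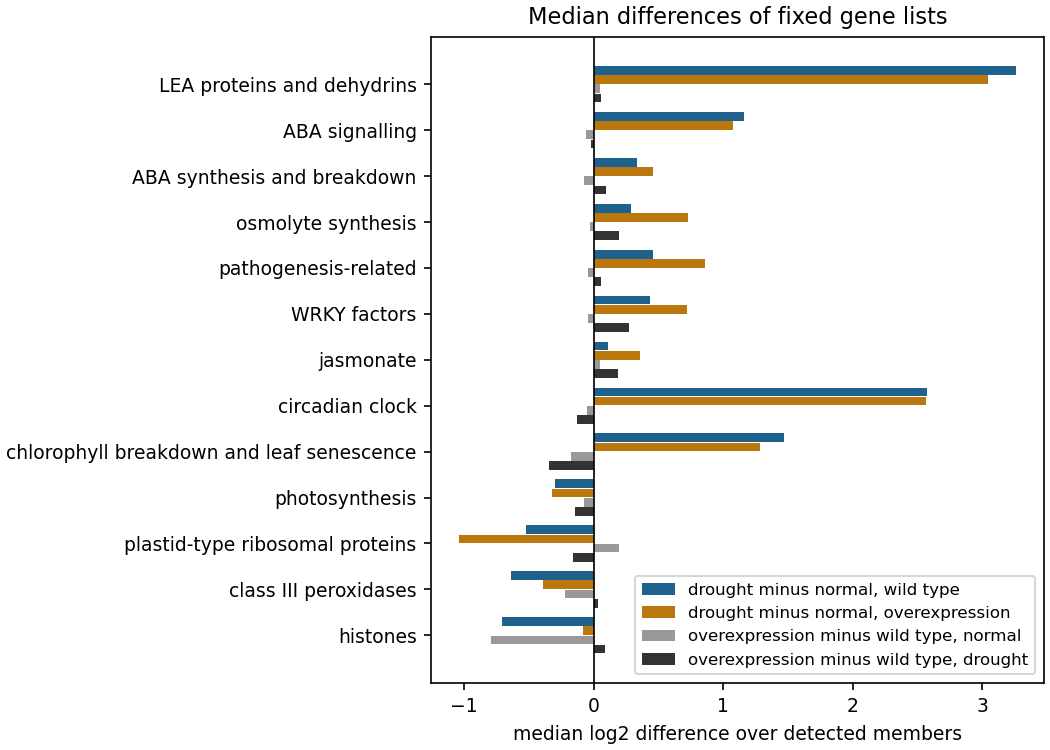
Median log2 difference (horizontal axis) over the detected members of 13 fixed gene lists in 4 comparisons, with bars from 0. LEA proteins and dehydrins stand at 3.26 and 3.05 for drought, and histones at -0.79 for overexpression plants under normal conditions.

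The difference of both drought responses was computed from all 4 arrays, as the response in overexpression plants minus that in wild type. Histones had a median of 0.87, with 20 of 47 members at least 2-fold higher and 0 lower. Their drought differences were -0.70 in wild type and -0.08 in overexpression plants, the latter turning positive under quantile normalization and in the authors' deposited table. The median of 0.87, that of the wild type drought response and that of the genotypes under normal conditions (-0.79) all use the wild type array under normal conditions, on which 31.7% of random and artificial control spots were well above background. Over the 46 members above background on every array compared the median was 0.86 here, with 19 higher, and -0.74 for the genotypes under normal conditions, with 15 lower. The genotype median under drought, which does not use that array, was 0.09. OsPR1a differed by -2.99 and OsKSL7 by -2.16, and plastid-type ribosomal proteins had a median of -0.39 with 0 of 47 past 2-fold. A gene described as the transcription factor MYBS3 (Os05g0442400) differed by 2.89 and the CcmA family gene Os04g0627200 by -4.56 (-2.55 with the common floor). Late embryogenesis abundant proteins had a median of -0.04, with 3 of 30 members higher and 3 lower, and 1 and 0 of the 24 above background on all arrays.

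Of 27100 genes 2711 were higher and 515 lower in this difference, and 951 and 307 of the 23835 above background on all arrays. With all arrays held at the common floor they were 955 and 346. These counts also use the wild type array under normal conditions, on which 31.7% of random and artificial control spots were well above background. The split was 1489 and 955 under quantile normalization, 667 and 305 with normexp correction, and 1518 and 982 in the authors' deposited table. Photosynthesis genes had a median of -0.07, which turned positive under quantile normalization and in that table. Diterpenoid phytoalexin genes had a median of -0.16, of -0.69 under quantile normalization and in that table, and positive with normexp correction and with the mean over probes.

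The genotype differences in both conditions were less alike than the drought responses. Their correlation across genes was 0.209 over 27100 genes and 0.199 over the 23835 on all 4 arrays. A total of 173 genes were higher in both conditions, where 13.2 were expected for independent lists, and 138 were lower in both, where 23.5 were expected. With each probe sequence counted once they were 131 and 121, where 11.0 and 21.7 were expected. Over the genes above background on all 4 arrays they were 98 and 28, where 3.08 and 2.86 were expected, and 61 and 20 with each sequence once. Genes at least 2-fold apart in opposite directions numbered 207 of the 27100, more than the 138 lower in both. Of these, 195 were lower under normal conditions and higher under drought. On all 4 arrays 20 were opposite, 16 of them in that way. Among genes that were higher under drought in wild type (3265), the median overexpression difference under drought was 0.0065, against -0.0063 from simulated noise and 0.0182 for the other genes, and -0.0007 with all 4 arrays above background. Among those lower (4404) it was 0.11, against 0.0063, and 0.0863 with all 4 arrays above background. That noise is technical only and leaves out the variation between plants. It was set for all genes from sequences above background (SD 0.094), whereas other sequences had an SD of 0.831. The simulated values are therefore too small for dim genes. Under median scaling the medians were -0.048 and 0.051, and with normexp correction the second was 0.036.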

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

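The common floor on dim signals, the counts with shared probe sequences set apart, the test of dim-probe noise and both clock tests were chosen only after the results were seen. None of the differences between groups listed here was tested, since each group is 1 array.

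In the drought response, 31 genes above background on all 4 arrays differed by at least 2-fold in opposite directions in both genotypes. In wild type and overexpression plants, in that order, the named ones were Os04g0627200 (1.09 and -3.47), Os07g0517600 (1.64 and -1.10), Os07g0589200 (-1.34 and 1.53), Os04g0608700 (1.32 and -1.88), Os02g0122900 (2.42 and -1.29), Os03g0733600 (-1.38 and 2.70) and Os08g0474000 (1.67 and -1.22). In the overexpression difference, 20 genes were opposite between normal conditions and drought. The named ones were Os04g0627200 (3.13 and -1.43), Os04g0444400 (1.08 and -2.05), Os03g0733600 (-2.24 and 1.84), Os06g0546500 (-1.78 and 1.37) and Os08g0230600 (-1.90 and 1.15). With the common floor 29 of the 31 and 15 of the 20 stayed apart in this way, while Os04g0627200 came to 0.26 in wild type drought and to -0.26 between genotypes under drought. List medians were opposite for cytosolic ribosomal proteins (-0.10 and 0.02, against -0.079 and 0.031 over all genes compared, and -0.045 and -0.028 under median scaling), plastid-type ribosomal proteins (0.20 and -0.16) and histones (-0.79 and 0.09). Random and artificial control spots (240 per array), which the comparisons do not use, were well above background more often than the 153 negative control spots on each array. The shares were 31.7% against 1.31% for wild type and 10.8% against 2.61% for overexpression plants under normal conditions. Under drought they were 10% against 0.654% and 22.9% against 1.31%.

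Under normal conditions 1730 genes were lower and 392 higher in overexpression plants, a ratio of 4.41, and 1197 of the lower genes were not well above background on the overexpression array. With all arrays held at a common floor the ratio was 1.67, and among the 12079 brighter genes it was 1.11 (59 lower and 53 higher). Among the 505 lower genes measured on all arrays, the median under drought was 0.15, which argues against a difference that persists in most. Of these, 28 were also lower under drought, where 2.86 were expected for independent lists. Lower genes that were dim on an array are not covered. Raised signal of dim probes on the wild type array may account for much of the excess. The floor cannot separate this from genes truly low in overexpression plants, since it removes both. Of the lower genes 69.2% were dim on the overexpression array, and of the higher genes 29.6% on the wild type array. What stays open is the remaining excess over dimmer genes and any genotype difference present under normal conditions alone, which was not tested.

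Genes that differed the same way between genotypes in both conditions numbered 126 on all 4 arrays, 21.2 times the 5.94 expected. Genes that differed in opposite directions numbered 20, so dim-probe noise is argued against for most of the 126. It is not excluded for single genes, since the expected number is not matched on signal and random control spots can pass the filter. The number was not computed with the common floor. Of the 126 genes, 123 had a locus, and 52 of these carried a probe sequence that another locus also has, 29 of them 1 sequence. Yet with each sequence counted once the number was 81, 16.8 times the 4.83 expected, so shared sequences could account for part of it only. Neighbouring pairs were counted over a wider set, the 294 loci that differed the same way and were above background on at least 1 array. Pairs within 5 places in locus order numbered 28 there. That was above the central 95% of signal-matched random sets and of subsets of drought genes, which both ended at 26 (maxima 33 and 34). The 123 loci were not counted apart. Over the 225 loci with a probe sequence of their own there were 19 pairs, against ends at 17 and 18 (maxima 23), and their share of such loci compared ran from 0.602% on chromosome 2 to 1.46% on chromosome 4. Differing chromosome segments of the plant lines may therefore account for some of the 294 loci and stay open, as does an effect of the transgene, which was not tested.

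Between the normal and drought arrays, OsLHY was lower (-2.99 in wild type and -3.13 in overexpression plants) while 6 of 7 later-peaking clock genes were higher in both genotypes. Between genotypes 0 of 9 clock genes differed by 2-fold in either condition, which argues against a genotype difference as large as that with drought. Their larger median between genotypes was -0.13, under drought, where 0 of 9 were higher. A smaller genotype difference is not excluded, since that median pools genes of opposite phase. Collection at another time of day could give the shift between normal and drought arrays, and so could an effect of drought on the clock. These cannot be told apart, because every drought array was collected later and the labels give no time of day.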

How the results depend on the processing

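The common floor and counting each probe sequence once were chosen after the data were seen, and every other alternative was set beforehand. Within a comparison no paired analysis was possible because each group is 1 array, and leaving out a replicate was not possible for the same reason. An additive fit of genotype and condition over the 4 arrays, which leaves 1 residual degree of freedom (the difference of both responses itself), was not run. OsDIS1 has no value under any setting. Of 120 gene counts under an alternative, 75 stayed within 1.5 times and 45 moved further. Of 1065 list medians 99 changed sign, 34 of them under median scaling, and 3 of the 99 had been at least 0.25 in size, the rest at most 0.21. Single genes and list medians counted as moved at a shift of the comparison's technical SD (0.094 to 0.132) or more, well below 1.5-fold. Correlations and the medians of drought-responsive genes did so at 0.05, and overlaps at 1.5 times. By these rules 831 of the list medians held and 231 moved without such a turn. Of 59 other main values 41 held and 18 moved. Of 3268 values of single genes and overlaps 1514 held, 1746 moved and 8, all of genes at least 2-fold apart, turned in sign. The technical SD of sequences not well above background was 0.64 to 1.04. Except where a threshold or filter changes which genes count by construction, the cause was not tested.

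In the lists here, N is overexpression against wild type under normal conditions, D the same under drought, W and X drought against normal conditions in wild type and overexpression plants, and I the difference of both responses. Under quantile normalization there were 1012 lower in N, and 1489 higher and 955 lower in I. With normexp correction there were 243 higher and 402 lower in N, 268 higher in D, 2809 lower in W, 3174 higher in X, and 667 higher and 305 lower in I. In the authors' deposited value table there were 1062 lower in N, and 1518 higher and 982 lower in I. With every array above background there were 533 lower in N, 341 higher and 171 lower in D, and 951 higher and 307 lower in I. Without a filter there were 503 lower in D, 5314 in X and 1822 in I. At 1.5-fold, higher and lower genes were 807 and 3264 in N, 1895 and 783 in D, 5821 and 7043 in W, 8216 and 5480 in X, and 4796 and 1411 in I. At 4-fold they were 172 and 471, 236 and 85, 1036 and 1354, 1433 and 757, and 795 and 145 in the same order. With the common floor there were 500 lower in N, 354 higher and 147 lower in D, and 955 higher in I.

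The correlation of the genotype differences was 0.261 under quantile normalization, 0.328 with normexp, 0.267 in the value table and 0.149 without a filter. That of the drought responses was 0.906 with normexp and 0.903 with every array above background. The genotype difference under drought of genes lower under drought in wild type was 0.051 under quantile normalization, 0.051 under median scaling, 0.036 with normexp and 0.047 in the value table, and that of genes higher was -0.048 under median scaling. OsLEA3 was higher under drought in W and X by 6.42 and 5.69 under median scaling and by 6.31 and 5.79 with normexp. With the mean over probes it was 5.97 in W, 0.21 in N and 0.17 in D.

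List medians of at least 0.25 that turned in sign were the nitrate and phosphate nutrition median in W (0.062, every array above background) and the seed storage and germination medians in N (0.42) and X (-1.02) without a filter. Single genes at least 2-fold apart that turned were OsKSL4 in I (-0.021, quantile normalization), Os09g0369400 (-0.023), Os12g0127600 (-0.057), Os02g0770800 (-0.04) and Os03g0136400 (-0.18) in D and Os03g0136400 in I (-0.055), all with normexp, and Os05g0134700 in D (-0.21) and Os05g0399700 in I (-0.17) with the mean over probes.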

Other observations

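Heat shock proteins and factors did not move as a block under drought, with 22 of 156 members at least 2-fold higher and 25 lower in wild type, and 23 and 20 of 158 in overexpression plants. Single members differed strongly in both, such as a DnaJ-domain gene (Os01g0606900, 6.81 and 6.21) and the chaperone gene for heat shock protein 82 (Os09g0482600, 5.43 and 5.36). Glutathione S-transferases, which conjugate toxic compounds, had 12 of 65 members higher and 14 lower in wild type (11 and 8 of the 58 above background on both arrays) and 14 and 11 of 61 in overexpression plants. Antioxidant enzymes were higher for 5 of 38 members and lower for 2 in wild type and higher for 6 in overexpression plants, with catalase A (Os02g0115700) at 2.25 and 1.78. Aquaporins, which pass water through membranes, had 2 of 11 members higher and 2 lower in wild type, and 2 and 3 in overexpression plants. A tonoplast aquaporin (Os04g0527900) was higher by 2.35 and 2.49.

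Genes of the cell wall were lower for 15 of 62 members and higher for 7 under drought in wild type, and for 16 and 12 of 64 in overexpression plants (14 and 7 of the 54 above background on both arrays). An expansin (Os10g0542400) was higher by 3.56 and 3.67, and a xyloglucan-modifying enzyme (Os04g0604300) differed by -2.80 and -2.18. Among low-oxygen genes, 2 of 9 were higher and 1 lower in wild type, and 2 and 3 in overexpression plants, with a pyruvate decarboxylase (Os05g0469800) at -3.38 and -2.70. Seed storage and germination genes were higher for 6 of 24 members and lower for 5 in wild type (5 and 0 of the 18 above background on both arrays), and for 7 and 2 of 19 in overexpression plants. Of 5 root markers 3 were detected, with 2 lower in wild type (1 of the 2 above background on both arrays) and 0 in overexpression plants. Of the shoot meristem markers, 1 of 3 was higher in wild type (OSH15, at least 13.6-fold, or 3.07-fold with the common floor), and 0 of 2 in overexpression plants.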
